A study of Mus musculus with 6 samples.

How the data were processed

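Kidney RNA from 6 newborn mice was labelled with Cy3 and hybridised to single-colour Agilent mouse arrays, 1 array per neonate, per the labels. The deposited files are scanner output of Agilent Feature Extraction, version 11.0.1.1 per the file headers and 9.1 per the submitters' processing notes, and the difference was not resolved. The deposited intensity of each spot is linear, background-subtracted and not normalised between arrays, per the file headers. The files also give flags for outliers, saturation and signal well above background, and the headers the scan date of each array. Arrays with the same scan date were taken to share a slide, and slide is meant in that sense throughout.

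Each array held 44397 spots, of which 1377 controls were left out. Spots flagged as outliers were removed, log2 of the processed intensity was taken, each array's 75th percentile over non-control spots was subtracted, and spots of a probe were averaged. Accessions of 27234 of 39429 probes (69.1%) matched a gene in a RefSeq table of assembly GRCm38.p6, giving 20659 named genes. The headers name build mm9 for the array design, so that table was used only for names, for which genes neighbour each other and for the chromosome a gene lies on. Of the unnamed probes, 3218 carried Ensembl accessions. A probe entered if well above background on all arrays of at least 1 group, and the brightest such probe stood for its gene, which left 21207 genes, 15185 of them named.

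Groups came from the labels. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes, threshold 0.05). With 3 arrays against 3 the smallest two-sided exact permutation p of a single value is 0.1. Gene lists with at least 5 measured members, 63 of 64, were tested with camera at its preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives. The list of sex chromosome genes had too few measured members, and its probes are given per array without the filter. The design, the alternatives, the lists and the rule for named genes were fixed before the data were examined. The rule named Usp10, up to 10 genes per direction with the largest change among those past the threshold whose groups did not overlap, completed by the smallest unadjusted p, leaving out clone and predicted names, and up to 4 members with the smallest p of each list described. All members of the lists of Usp10 partners, Usp10 neighbours, housekeeping and sex chromosome genes could be named.

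The alternatives were quantile normalisation, scaling on the array median, normexp background correction with an offset of 50 followed by either scaling, no filter or a stricter filter on dim probes, the mean of a gene's probes, every probe on its own, an intensity trend with robust variance, array weights, a replicate block, a slide block, leaving out each array, and other thresholds. The files held no mean signal, so normexp used the median signal and the median background in its place. The offset is added to every signal, which makes differences between dim signals smaller. Chosen after the data were seen were the slide block without WT replicate 2, slide 1 alone, the arrays labelled KO against WT replicate 3 alone, and the slide block with an intensity trend.

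The fits were tested on simulated data, 10 sets of 21207 genes with the real means and slide differences and 200 genes changed. The fit without a block recovered 8.51% of changes of 1 on the log2 scale, 82.7% of changes of 2 and 95.8% of changes of 3, with 0.401% false calls. With slide as a block the shares were 71.5%, 99.4% and 99.8%, with 7.83% false calls. A shift of 0.6 in the interferon list was found in all 10 sets. The simulated noise was drawn independently for each gene and array, with the residual spread of the slide-block fit. It held no correlation between genes and no sample structure besides slide, so these shares need not hold for the real arrays. No coordinates are given, since the build of the array design and that of the table differ.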

Results

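Kidney RNA of newborn mice was measured on 6 single-colour expression arrays, 3 from neonates labelled Usp10 knockout (KO) and 3 from neonates labelled wild type (WT), collected about 6 hours after birth. Usp10 encodes a deubiquitinating enzyme. The design text describes separate neonates within each genotype, and the comparison it implies asks which kidney transcripts differ between the genotypes. Between 64.4% and 73.9% of the 43020 non-control spots were well above background on each array, and no spot was saturated. The number of arrays, 3 per group, limits the precision of every value given here. By scan date the arrays fell into 2 groups, taken as 2 slides. KO replicates 1 and 2 and WT replicates 2 and 3 were on slide 1, and KO replicate 3 and WT replicate 1 on slide 2. On KO replicate 2 the brightest 1% of spots held 39.1% of the signal, against 29.4% to 32.0% on the other 5 arrays. Across genes, which are not independent replicates, KO replicate 1 and WT replicate 2 correlated at 0.993 and KO replicate 3 and WT replicate 1 at 0.989, above the highest value among pairs labelled KO (0.982), while WT replicates 2 and 3 correlated at 0.990. Values without a single array are given where they moved by over 1.5 times.

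The Usp10 transcript was read by 1 probe, which targets NM_009462, and its signal went against the labels. On the log2 scale relative to each array's 75th percentile it stood at 3.52 ± 0.14 (SD, n = 3) on the arrays labelled KO and at 3.03 ± 0.09 (SD, n = 3) on those labelled WT. The signal was higher on all 3 arrays labelled KO, by 0.49 ± 0.16 (SE) on the log2 scale, but did not pass the limma test over all genes (adjusted p = 0.416, and 0.224 with slide as a block). The log2 difference was 0.47 within slide 1 and 0.55 within slide 2. Which part of the gene was removed is not given in the sources used here, so the probe may lie outside it and then checks nothing. Groups are therefore named by their labels, and every direction below rests on those labels.

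All 6 samples are labelled male, but sex-linked transcripts differed within the group labelled WT. The Y-linked genes Ddx3y, Eif2s3y and Uty were well above background on 5 arrays and not on WT replicate 2, where Eif2s3y stood at -8.11 against 1.83 on WT replicate 3. The brighter probe of Xist, the RNA that coats the inactive X chromosome of females, was well above background on WT replicate 2 (0.43) and WT replicate 1 (-0.62) and on none of the other 4 arrays. The dimmer Xist probe was above background on WT replicate 2 alone (-3.90). WT replicate 1 therefore gave both Xist and Y-linked signal. Whether this array holds RNA of a single animal cannot be told from these values. The number of independent neonates in the group labelled WT therefore rests on the labels. WT replicate 3 was the only array labelled WT with Y-linked signal and no Xist signal above background, and the differences against it alone, where this single array is assumed to vary like the others, are given beside the gene groups.

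**Figure D1:**
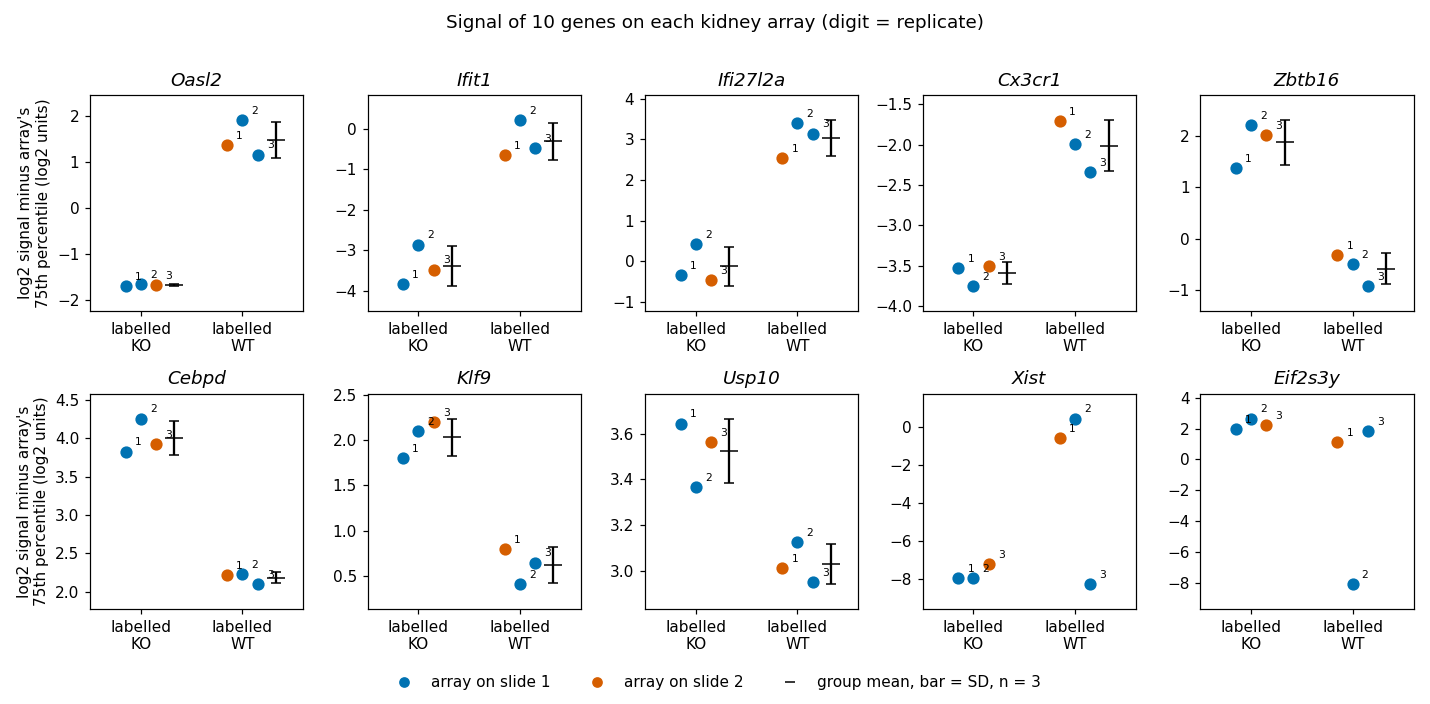
Normalised log2 signal (vertical axes, log2 units relative to each array's 75th percentile) of 10 genes on each array, with colour for the slide, a digit for the replicate, and black bars for the group mean and SD (n = 3), omitted for the sex-linked genes. Oasl2, Ifit1, Ifi27l2a and Cx3cr1 lie lower and Zbtb16, Cebpd, Klf9 and Usp10 higher on all 3 arrays labelled KO, whereas Xist is above background on WT replicates 1 and 2 and Eif2s3y is missing from WT replicate 2.

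Of 21207 genes tested, 17 passed an adjusted p of 0.05 in limma, 4 higher and 13 lower on the arrays labelled KO, with adjusted p between 0.0242 and 0.0488. For each of them all 3 arrays labelled KO lay on one side of all 3 labelled WT. The largest falls were in antiviral genes that interferon induces. Ifi27l2a was 8.88-fold lower, Oasl2 8.83-fold lower and Ifit1 8.43-fold lower, with log2 differences of -3.15 ± 0.31, -3.14 ± 0.22 and -3.07 ± 0.32 (SE). Ifi211, Oas1a, Trim30d and Xaf1 also fell, by log2 differences between -2.20 and -1.94. With normexp background correction and the 75th percentile the differences of Ifit1, Ifi211, Xaf1 and Trim30d were -1.90, -1.46, -1.29 and -0.74, and Trim30d no longer passed (adjusted p = 0.303). With the mean of a gene's probes Ifit1, Ifi211, Trim30d, Oas1a and Xaf1 did not pass, with adjusted p between 0.0521 and 0.127. The log2 differences of Ifit1, Ifi211 and Trim30d were unchanged there (-3.07, -2.20 and -1.98), while those of Oas1a and Xaf1 were -2.42 and -1.59. Ifi209, Cpa3, a carboxypeptidase of mast cells, and the chemokine gene Ccl7 were not well above background on any array labelled KO. They were at least 1.78-fold, 1.78-fold and 1.67-fold lower. Such bounds compare the brighter group's mean with the higher of the dim probe's own signal and the lowest signal called well above background on each array. They leave out sampling error and a probe's own detection limit, so here and below they are estimates and not strict limits. With normexp background correction and the 75th percentile the log2 differences of Ifi209, Cpa3 and Ccl7 were 0.010, 0.067 and 0.064, where the median of all genes was 0.14. They were -0.39, -0.32 and -0.33 with normexp and quantile normalisation, and passed with neither. The offset in normexp makes differences between dim signals smaller, so neither setting gives the size of these differences. Ccl7 also did not pass with the mean of probes (limma adjusted p = 0.0521), with its log2 difference unchanged at -2.58.

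The 4 genes that rose were Zbtb16, Cebpd, Lpin1 and Upp2. Zbtb16, a zinc-finger transcription factor that glucocorticoids induce, was 5.49-fold higher (log2 difference 2.46 ± 0.27, SE). Cebpd, a transcription factor of acute responses, was 3.54-fold higher (1.82 ± 0.18) and the phosphatidate phosphatase gene Lpin1 2.75-fold higher (1.46 ± 0.17). Upp2, a uridine phosphorylase, was not well above background on the arrays labelled WT and was at least 2.24-fold higher, but its log2 difference was 0.64 with normexp and the 75th percentile and 0.25 with normexp and quantile normalisation, and it passed with neither. Lpin1 did not pass with quantile normalisation (adjusted p = 0.0519), array median scaling (0.0652), the mean of probes (0.0521) or normexp and quantile normalisation (0.114, log2 difference 0.86). Zbtb16 and Upp2 did not pass with the mean of probes (0.0521 and 0.0538), nor Zbtb16 and Cebpd with normexp and quantile normalisation (0.0940 and 0.0628). With the mean of probes the log2 differences of Zbtb16, Upp2 and Lpin1 were unchanged (2.46, 2.78 and 1.46). The next 6 by unadjusted p did not pass. Errfi1, Zmat3, Herpud1, Klf9 and Nr1h4 had log2 differences between 1.18 and 1.58, and Rgs1, not well above background on the arrays labelled WT, was at least 2.26-fold higher, but its log2 difference was 0.63 and 0.24 under the same normexp settings. Their adjusted p lay between 0.0513 and 0.0643, and between 0.0347 and 0.0465 with slide as a block.

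With slide as a block 62 genes passed, 26 higher and 36 lower, and these included all 17. With the same block another split of the 6 arrays, which on slide 1 set KO replicate 2 against the other 3 arrays, gave 305 genes. Within slides 1 and 2 the log2 differences were -3.19 and -3.04 for Oasl2 and 2.51 and 2.35 for Zbtb16. The groups did not overlap for 18.2% of genes, where chance gives 10% on average and the 9 other splits of the 6 arrays into 3 against 3 gave between 0.575% and 18.9%. The count of 17 fell to 0 without KO replicate 1, KO replicate 2, WT replicate 1 or WT replicate 2, to 1 without WT replicate 3 and to 13 without KO replicate 3, of which 6 were among the 17. Of the 17, 9 passed with normexp and the 75th percentile, 7 with the mean of a gene's probes, and 0 with normexp and quantile normalisation or with no filter on dim probes, where limma gave 2245 and 2052 genes at an unadjusted p under 0.05. Against WT replicate 3 alone limma called 0 genes, with 1839 at an unadjusted p under 0.05, while the log2 differences of Oasl2 and Zbtb16 were -2.82 and 2.80. By the second criterion, an absolute log2 difference of at least 1 and an unadjusted p under 0.05, 224 genes were higher and 134 lower.

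Of 63 gene lists fixed before the data were examined, 12 passed an adjusted p of 0.05 in camera with its preset correlation between genes, 6 higher and 6 lower. None passed with an estimated correlation, where the lowest adjusted p was 0.392 and 4 had an unadjusted p under 0.05. By fry, which asks whether a list's genes move on balance one way, 3 lists passed, namely the interferon, macrophage and dendritic cell, and circadian clock lists (adjusted p = 0.0374 for each). With slide as a block fry called 0 lists, with a lowest adjusted p of 0.0626 and 16 lists at an unadjusted p under 0.05.

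Interferon-induced genes were lower as a group on the arrays labelled KO. Of 37 measured members 35 had a negative difference, 6 passed over all genes, or 12 with slide as a block, and 26 were lower when adjusted over the list alone. The median log2 difference was -1.17, with -1.38 within slide 1, -0.97 within slide 2 and -1.09 against WT replicate 3 alone (camera adjusted p = 1.04e-29, 2.83e-25 with slide as a block, adjusted p = 0.392 with an estimated correlation). The list's member B2m, which is also on the housekeeping list, stood at 2.25 ± 0.29 (SD, n = 3) on the arrays labelled KO and 3.25 ± 0.05 (SD, n = 3) on those labelled WT, and passed when adjusted over either list alone but not over all genes (adjusted p = 0.172). Usp18, an interferon-induced protease that removes ISG15, differed by -2.37 ± 0.40 (adjusted p = 0.119), and by -1.27 with normexp and the 75th percentile.

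Macrophage and dendritic cell markers were lower by a smaller amount. Of 20 measured members none passed over all genes, where 9 had a negative difference at an unadjusted p under 0.05, and 4 were lower when adjusted over the list alone. These were the fractalkine receptor gene Cx3cr1 (-1.58 ± 0.21), the Fc receptor gene Fcgr1 (-1.28 ± 0.32) and the complement genes C1qc (-0.87 ± 0.24) and C1qa (-0.77 ± 0.21), all as log2 difference ± SE. Cx3cr1 passed over all genes with slide as a block (adjusted p = 0.0349). With normexp and the 75th percentile the differences of Cx3cr1, Fcgr1 and C1qa were -0.63, -0.49 and -0.052, and the list's median was -0.20. Without that correction the list's median was -0.39, with -0.47 within slide 1, -0.33 within slide 2 and -0.54 against WT replicate 3 alone, where the adjusted p was 0.0498 (camera adjusted p = 7.06e-05, 0.000433 with slide as a block, adjusted p = 0.392 with an estimated correlation).

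Glucocorticoid-response genes were higher as a group. Of 28 measured members 2 passed over all genes, Cebpd and Zbtb16, and 12 were higher when adjusted over the list alone, among them Errfi1 (1.58 ± 0.19) and Klf9 (1.41 ± 0.19), which both passed over all genes with slide as a block. The median was 0.61, with 0.67 within slide 1, 0.57 within slide 2 and 0.65 against WT replicate 3 alone (camera adjusted p = 1.89e-10, 7.86e-09 with slide as a block, adjusted p = 0.494 with an estimated correlation). With KO replicate 1 and WT replicates 2 and 3 set against the rest, the median was -0.60. That split puts both arrays of slide 2 on the same side, and slide was not a term. On the circadian clock list, which shares Per1 with the glucocorticoid list, 3 of 15 measured members were higher when adjusted over the list alone. These were Per1 (1.48 ± 0.28), Nfil3 (0.74 ± 0.17) and Tef (0.66 ± 0.19). The clock list's median was 0.37, with 0.39 within slide 1 and 0.28 within slide 2 (camera adjusted p = 0.00308, 0.00642 with slide as a block, adjusted p = 0.393 with an estimated correlation), and against WT replicate 3 alone it was 0.27 and no longer passed (adjusted p = 0.0781).

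Targets of the tumour suppressor p53 were higher in 7 of 38 measured members when adjusted over the list alone and in none over all genes, where 11 had an unadjusted p under 0.05. The smallest p were those of Zmat3 (1.36 ± 0.17), Ddit4 (1.48 ± 0.21), Trp53inp1 (1.58 ± 0.24) and Cdkn1a (1.30 ± 0.20). With slide as a block Zmat3 and Trp53inp1 passed over all genes (adjusted p = 0.0370 and 0.0450). Ddit4 and Cdkn1a were also on the glucocorticoid list. The median was 0.27, with 0.27 within slide 1, 0.31 within slide 2 and 0.37 against WT replicate 3 alone, and 0.18 with normexp and quantile normalisation (camera adjusted p = 7.06e-05, 0.000186 with slide as a block, adjusted p = 0.494 with an estimated correlation). Cell cycle and mitosis genes had a negative difference in 48 of 49 measured members, none of which passed singly, with 10 at an unadjusted p under 0.05. Examples were the spindle genes Tpx2 (-0.75 ± 0.21) and Ttk (-1.08 ± 0.39, or -0.13 with normexp and the 75th percentile). Their median was -0.32, with -0.39 within slide 1, -0.29 within slide 2 and -0.37 against WT replicate 3 alone, and it was -0.18 without KO replicate 2 (camera adjusted p = 3.27e-09, 7.86e-09 with slide as a block, adjusted p = 0.613 with an estimated correlation).

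All 11 measured urothelial genes had a positive difference, 3 of them past the threshold when adjusted over the list alone, namely Krt20 (1.25 ± 0.26), Foxa1 (0.85 ± 0.23) and Upk1a (0.70 ± 0.20). The median was 0.51, with 0.51 within slide 1 and 0.54 within slide 2 (camera adjusted p = 0.000246, 0.000641 with slide as a block, adjusted p = 0.606 with an estimated correlation), but 0.34 without KO replicate 2 and 0.21 against WT replicate 3 alone, where the call was lost (adjusted p = 0.415). Immediate early genes had a median of 0.26, with 0.25 within each slide, and 2 of 32 members, Errfi1 and Gadd45g (1.08 ± 0.24), passed when adjusted over the list alone (camera adjusted p = 0.0297, 0.0239 with slide as a block, adjusted p = 0.494 with an estimated correlation). The call was lost without KO replicate 3 (adjusted p = 0.123) or WT replicate 2 (0.142) and against WT replicate 3 alone (median 0.30, adjusted p = 0.119). It was also lost with normexp and the 75th percentile (0.107) and with no filter on dim probes (0.162), and the median was 0.15 with normexp and quantile normalisation. Of the 19 alternatives run for lists, the urothelial call held in 17 and the immediate early call in 13.

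No member passed singly on the remaining 4 lists. Ribosome biogenesis genes had a median of -0.16, with -0.18 within each slide (camera adjusted p = 0.0154, 0.0106 with slide as a block, adjusted p = 0.558 with an estimated correlation). Their call was lost without WT replicate 1 (adjusted p = 0.119) and against WT replicate 3 alone (median -0.23, adjusted p = 0.0786). Endothelial genes such as Sox18 (-0.75 ± 0.18) and Cdh5 (-0.54 ± 0.18) had a median of -0.14, with -0.034 within slide 1 and -0.14 within slide 2 (camera adjusted p = 0.0297, 0.0362 with slide as a block, adjusted p = 0.494 with an estimated correlation). Their call was lost without KO replicate 2 (adjusted p = 0.103), WT replicate 1 (0.179) or WT replicate 2 (0.104) and against WT replicate 3 alone (median -0.12, adjusted p = 0.719), and the median was -0.040 without KO replicate 1 and -0.0071 with normexp and the 75th percentile. Oxidative phosphorylation genes had a median of 0.17, with 0.17 and 0.16 within slides 1 and 2, and smooth muscle, pericyte and juxtaglomerular genes one of -0.24, with -0.31 and -0.21. Both lost their call with slide as a block (camera adjusted p = 0.0302 and 0.0422, 0.0525 and 0.0818 with the block, adjusted p = 0.901 for both with an estimated correlation). The oxidative phosphorylation call was also lost without KO replicates 1 (adjusted p = 0.117) or 2 (0.110) or WT replicates 1 (0.158) or 3 (0.0843), and in each other scaling run, with medians between 0.036 and 0.14. With no filter on dim probes it was lost too (camera adjusted p = 0.156), and it held in 7 of the 19 alternatives run for lists. Against WT replicate 3 alone the median of this list was 0.26. The smooth muscle call was lost without KO replicate 2 (median -0.0055, adjusted p = 0.813), WT replicate 1 (0.184) or WT replicate 2 (median -0.37, adjusted p = 0.0802) and against WT replicate 3 alone (median -0.40, adjusted p = 0.453), and without KO replicate 1 its median was -0.45. It was also lost with array median scaling (adjusted p = 0.0809). Of the 19 alternatives run for lists, the smooth muscle call held in 11 and the endothelial call in 14.

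**Figure D2:**
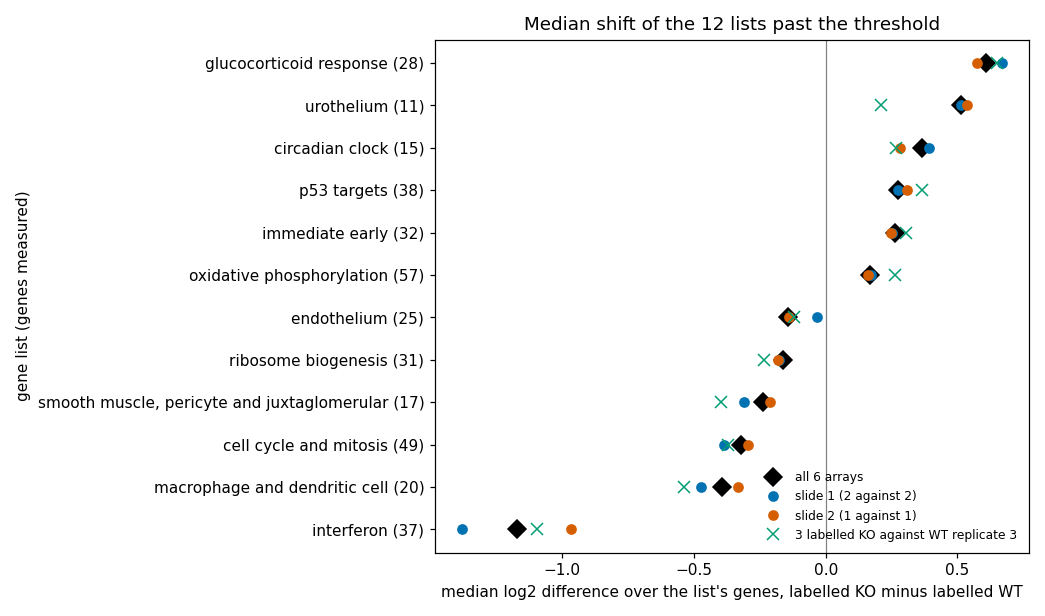
Median log2 difference, labelled KO minus labelled WT (horizontal axis, log2 units), over the measured genes of each of the 12 lists past the threshold (vertical axis), for all 6 arrays, within each slide, and for the arrays labelled KO against WT replicate 3 alone. The interferon list lies lowest, at -1.17, and the glucocorticoid list highest, at 0.61, and urothelial genes fall from 0.51 to 0.21 against WT replicate 3 alone.

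The other 51 lists did not pass, with medians between -0.42 and 0.30. Among nephron cell types, podocyte genes had a median of -0.30 (camera adjusted p = 0.157), proximal tubule genes -0.15 (0.109) and nephron progenitor genes -0.089 (0.324). With normexp and the 75th percentile the podocyte and progenitor medians were 0.013 and 0.044, against 0.14 over all genes. Without KO replicate 2 the podocyte and proximal tubule medians were -0.050 and 0.041. Both lists passed without KO replicate 1 (medians -0.42 and -0.22, adjusted p = 0.0103 and 0.000758) and without KO replicate 3 (-0.19 and -0.17). Podocyte genes passed in 4 of the 19 alternatives run for lists and proximal tubule genes in 6. Named examples were Clic5 (-0.63 ± 0.22) of podocytes, Acsm2 (0.73 ± 0.18) and Kap (-1.06 ± 0.35) of the proximal tubule, and the progenitor transcription factors Cited1 (-0.68 ± 0.20) and Six2 (-0.67 ± 0.33, or -0.38 without KO replicate 2), none of which passed. The progenitor median was -0.034 without KO replicate 2, -0.18 without WT replicate 2 and 0.015 without WT replicate 3, and without the latter the podocyte and proximal tubule medians were -0.18 and -0.089. Among 30 partners and reported substrates of Usp10 none passed, the median was -0.079 (camera adjusted p = 0.443) and 0.076 with normexp and the 75th percentile, and the stress-granule genes Caprin1 and G3bp2 differed by -0.65 ± 0.22 (-0.39 with the mean of probes) and -0.41 ± 0.18. That median was -0.052 without KO replicate 1, -0.037 without KO replicate 3, -0.14 without WT replicate 1 and -0.0072 without WT replicate 3. Of 28 measured genes that neighbour Usp10 on chromosome 8, Osgin1 (-1.05 ± 0.18, or -0.45 with normexp and the 75th percentile) and Crispld2 (0.83 ± 0.16) passed when adjusted over the list alone, and the list did not pass (adjusted p = 0.569). Housekeeping genes had a median of 0.10 and did not pass (adjusted p = 0.799).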

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

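The alternatives without WT replicate 2 under the slide block, on slide 1 alone, against WT replicate 3 alone, and with slide block and intensity trend together were chosen after the data were seen. The count of 17 genes stayed within 1.5 times with quantile normalisation, array medians, normexp with the 75th percentile, and the second threshold at adjusted p. Of the 17, normexp with the 75th percentile shared 9, gave 11 higher and 13 lower, against 4 and 13, and moved the median of all genes from 0.028 to 0.14. The count was 45 with an intensity trend and robust variance, 36 with array weights, 62 with slide as a block, 119 with the block and trend, and 27 with every probe on its own, and each of these held all 17. It was 8 with the mean of probes and 1 with signal required on all 6 arrays. It was 81 at an adjusted p of 0.1 and 358 at a log2 difference of 1 with an unadjusted p under 0.05, both looser by construction. In limma it was 0 with normexp and quantile normalisation, 0 without a filter, 0 with the slide block and WT replicate 2 left out and 0 against WT replicate 3 alone, with 2245, 2052, 5137 and 1839 genes at an unadjusted p under 0.05, and it was 1 on slide 1 alone. The settings that leave out arrays hold fewer samples, and the cause of the other shifts was not tested. Leaving out each array in turn gave 0 to 13 genes (0 without KO replicates 1 or 2 or WT replicates 1 or 2, with 2689, 1317, 1650 and 2484 at an unadjusted p under 0.05), 0.43 to 0.57 for the log2 difference of Usp10 and 9 to 16 lists.

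With replicate number as a replicate block limma called 0 genes, with 1609 at an unadjusted p under 0.05, and 14 lists. Deviations from the group means correlated at -0.40, 0.48 and -0.60 across genes for replicates 1, 2 and 3, so the numbers do not pair the samples. KO replicate 3 and WT replicate 1, which share a slide, correlated at 0.89.

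The 12 lists became 0 with an estimated correlation, 3 with fry and 6 against WT replicate 3 alone, and stayed within 1.5 times in every other setting run. Usp10 stayed higher and short of the threshold in every setting run, with adjusted p between 0.167 and 0.920. Interferon, glucocorticoid, p53, cell cycle and macrophage lists kept their direction and their camera call with the preset correlation in all 19 settings run for lists. Under normexp with the 75th percentile, Ifi209 (0.010), Cpa3 (0.067) and Ccl7 (0.064) changed sign, as did the medians of the podocyte (0.013), nephron progenitor (0.044) and Usp10 partner (0.076) lists. All of these values lay below the median of all genes in that setting, 0.14. With normexp and quantile normalisation Ifi209, Cpa3 and Ccl7 stayed lower (-0.39, -0.32 and -0.33). The signals of these 3 genes were not well above background on the arrays labelled KO. The offset in normexp makes such dim differences smaller, so these signs do not decide the direction. Leaving out each array, the proximal tubule median ran from -0.22 to 0.041 (without KO replicate 2) and the nephron progenitor median from -0.18 to 0.015 (without WT replicate 3). Over all settings the other values of 60 named genes kept direction and side of the threshold in 1012 instances, lost the call in 185 and gained it in 55, and those of 17 lists in 264, 36 and 18. Most of these 60 genes had no call with the main settings, so many kept sides are genes that stayed short of the threshold. Of the named genes with a call, Oasl2 passed most often, in 10 of 21 alternatives, and Lpin1 least often, in 5 of 21.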

Other observations

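The tests of slides and both tests of the Usp10 probe were chosen after the result was seen, and single genes of the interferon and macrophage lists had been seen before the test of leukocytes. Several metabolic genes stood out on lists that did not pass as a whole. On the gluconeogenesis and fasting list 5 of 24 measured members were higher on the arrays labelled KO when adjusted over the list alone, among them Klf15 (log2 difference 2.06 ± 0.38, SE), a regulator of amino acid breakdown, the insulin receptor substrate gene Irs2 (0.60 ± 0.15) and Ppargc1a (0.75 ± 0.19), a coactivator of mitochondrial genes. None passed over all genes, the list's median was 0.045, its mean 0.30 and its camera adjusted p 0.0952 (adjusted p = 0.597 with an estimated correlation). It passed in 8 of 19 alternatives, among them without KO replicate 2 (median 0.18, adjusted p = 0.0212), WT replicate 1 (0.11, 0.0285) or WT replicate 3 (0.10, 0.0297). Without KO replicate 3 the median was 0.15 and the list did not pass. Klf15 is also on the glucocorticoid list. The hexokinase gene Hk2 (1.87 ± 0.27) and the sterol sensor gene Insig1 (1.08 ± 0.16) passed when adjusted over their lists alone. Over all genes neither passed with the default limma settings. Hk2 passed in 3 of 21 alternatives, one of them normexp with the 75th percentile (adjusted p = 0.0431), and Insig1 passed with slide as a block (adjusted p = 0.0450), but its log2 difference was 0.65 with normexp and the 75th percentile and 0.40 with normexp and quantile normalisation. Among 46 deubiquitinases, Usp2 (1.35 ± 0.19) and Usp18 (-2.37 ± 0.40) passed over the list alone in opposite directions, and Usp2 passed over all genes with slide as a block (adjusted p = 0.0498).

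In WT replicate 1 the brighter Xist probe gave 48.3% of its signal in WT replicate 2. The dimmer Xist probe, not above background in WT replicate 1, gave 22.8%. Eif2s3y gave 61.9%, Ddx3y 63.5% and the Uty probes 54.2% and 58.6% of their signal in WT replicate 3. Relative to the mean of the arrays labelled KO, these were 45.0%, 62.2%, 47.1% and 54.3%.

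Interferon-induced genes were lower on the arrays labelled KO. Fewer macrophages and dendritic cells, as the whole cause through the transcripts these cells carry, is argued against for these arrays. Their markers had a median of -0.39 and the interferon list one of -1.17. None of these markers is on the interferon list. The interferon median minus the marker median was -0.78 (95% bootstrap interval over genes -1.17 to -0.35). That interval holds the arrays fixed and does not measure variation between mice. A loss of such cells that lowers interferon-induced genes in other cells stays open, because the medians do not test it. Cx3cr1 (-1.58) and Fcgr1 (-1.28) fell at least as far as the interferon median, while 5 of the 20 markers had a positive difference. A constant offset between slides cancels, because both groups held the same number of arrays on each slide. The within-slide medians of the interferon list were -1.38 and -0.97. Variants linked to the Usp10 locus stay open: the 26 members lower at an unadjusted p under 0.05 lay on 12 chromosomes other than 8, with 2 on chromosome 8, but the interferon regulator gene Irf8 is a neighbour of Usp10 (log2 difference -0.29 ± 0.17) and could act on genes elsewhere, so the spread over chromosomes does not exclude them. Sex stays open too, since Xist was above background only in 2 arrays labelled WT, although the median against WT replicate 3 alone was -1.09. An effect of the genotype is a hypothesis that these data do not separate from these, and the Usp10 probe did not bear out the labels.

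Glucocorticoid-response genes were higher on the arrays labelled KO. A median of similar size, -0.60, also arose with KO replicate 1 and WT replicates 2 and 3 set against the rest. A constant offset between slides cancels in the difference between groups, because both groups held the same number of arrays on each slide. The within-slide medians were 0.67 and 0.57. Collection at a different time of day stays open. The median absolute difference of the clock genes without Per1 and Bhlhe40, 0.37, lay at the 96.5 percentile of 10000 random lists matched on level, whose 95th percentile was 0.35. Any shared influence on the clock genes could give such a value, so the test does not single out time of day. Adrenal tissue taken with the kidney stays open, because the adrenal list's median of -0.051 had a 95% bootstrap interval from -0.20 to 0.44, and of its marker genes Star (0.41), Cyp11a1 (0.35) and Cyp21a1 (-0.086) were above background on 3, 0 and 6 arrays. The gluconeogenesis and fasting list and the fatty acid oxidation list did not pass (adjusted p = 0.0952 and 0.754), which does not exclude fasting.

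The Usp10 probe was higher on the arrays labelled KO. Scaling of the arrays is argued against, since the difference was between 0.39 and 0.49 under 5 scalings and the lowest ratio to its standard error was 2.35. These scalings used the same arrays, and the rise passed the limma test over all genes in no setting run. No true difference therefore stays open. Whether KO and WT labels were exchanged or the probe lies outside the removed part cannot be told apart, because 0 other Usp10 probes were on the array and no other value tells the genotypes apart.

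The 6 arrays allow 10 splits into 3 against 3, too few for a share under 0.05. The real split gave 17 genes and the highest other split 0, so 1 split gave as many. At an unadjusted p under 0.05 the real split gave 2202 genes and 3 of the 9 other splits gave more, up to 2807. In all 3 both arrays of slide 2 lay on the same side, and these fits held no slide term. In fits with slide as a block, run on the splits after the result was seen, the real split gave 62 genes and the highest other 305, with 3764 and 3962 at an unadjusted p under 0.05. That other split had KO replicates 2 and 3 and WT replicate 1 on one side. With the block it rests on KO replicate 2 against the other 3 arrays of slide 1. Its count can show that this array differed from them, and it is not a contrast of the same form as the real split. Without KO replicate 2 limma called 0 genes, with 1317 at an unadjusted p under 0.05. For lists the real split gave 12 and the highest other 20, and 4 of the 10 splits gave as many.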
